A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

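Total RNA from 3 cell lines was measured on Affymetrix whole-transcript arrays after exposure to single-walled carbon nanotubes (SWCNT) or to water alone. A549 is a human lung adenocarcinoma line of alveolar epithelial origin, THP-1 is a human monocytic leukaemia line, and J774 is a mouse macrophage line. The mouse sample titles spell the line J744 and their source labels spell it J774; it is called J774 here. Per the labels, cells grown in flasks to 80% confluency received 10 µg SWCNT per mL of medium for 24 hours, and control flasks received the same volume of distilled water. THP-1 cells had been treated with phorbol ester (PMA) for 48 hours, which turns these monocytes into macrophage-like cells. RNA was isolated with a Qiagen column kit and 100 ng was labelled with biotin using an Ambion whole-transcript kit, per the labels' protocols.

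Each of the 6 groups held 2 arrays, 12 in all, of which 8 were human and 4 were mouse. The labels number the arrays of a group 1 and 2 and do not state that they came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value. The deposited values are log2 expression summaries with 1 value per probe set, a unit taken from their range and from nearly equal quantiles across arrays. Per the submitters' processing notes they were made with Affymetrix Expression Console. Its version, the summary method, the normalization, the background correction and the annotation release are not given in the sources used here. Human and mouse values stand in separate tables that were normalized apart from each other, so every test was run within a table. Array medians lay between 7.81 and 7.90 in the human table and between 7.43 and 7.46 in the mouse table. The lowest values were 4.36 in the human table and 4.52 in the mouse table. Changes of dim genes near these floors are compressed. No scan date or array batch was used, because the labels give none.

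Gene names came from the platform annotation supplied with the data. Of 28869 human probe sets, 19310 had 1 gene symbol, 1752 had several and 7807 were unnamed. Entrez identifiers of 19279 human probe sets were found in a current human gene table, and 0 symbols needed updating. Of 28853 mouse probe sets, 21789 had 1 symbol, 1621 had several and 5443 were unnamed, and their symbols were kept as given. Probe sets with several symbols named no gene. Where a gene had several probe sets, the one with the highest mean over the table was kept, which left 18377 human and 19938 mouse genes. A gene was tested when the mean of at least 1 group lay above the 30th percentile of its table, a log2 value of 6.77 for human and 6.44 for mouse arrays. This left 15697 human and 15044 mouse genes.

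Differences were tested on the log2 scale with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The 8 human arrays entered 1 fit of group means with 4 residual and 6.04 prior degrees of freedom. The 4 mouse arrays entered their own fit with 2 residual and 2.26 prior degrees of freedom. The difference between the THP-1 and A549 responses was the interaction contrast of the human fit. Errors printed after ± are the model's standard errors. A set of 29 gene lists of pathways and 6 lists of cell type markers was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 35 lists. Camera with the correlation estimated from the data and limma's fry were run beside it. The version with an estimated correlation uses the residual degrees of freedom of the fit, 4 or 2, and the preset version many more. Its p-values can therefore be larger even where the estimated correlation lies below 0.01. For cholesterol biosynthesis in A549 that correlation was -0.0432, and camera's p rose from 1.2e-10 to 0.00219. A call lost with it need not mean correlated genes. Camera asks whether a list moves more than the other genes, and fry whether its genes move in 1 direction on balance. Members were also counted with p-values adjusted over the list alone. Overlaps between lines were tested with a two-sided Fisher's exact test, and human and mouse genes were matched by symbol for correlations across genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

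The tests, the gene and marker lists, the filter, the rule for naming genes and all alternatives not said to be added later were chosen before the data were examined. In each human line the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold were named. For J774, where no gene passed, the 10 largest each way at an unadjusted p under 0.05 were eligible. For a gene list, up to 4 members with the largest change were named, for the difference between human lines the 5 largest each way, and for genes shared by both human lines up to 10 per direction. Symbols with the usual prefixes of microRNAs, nucleolar and spliceosomal RNAs, olfactory receptors and provisional genes were passed over, which leaves in small Cajal body RNAs. Members whose call was lost when an array was left out were mostly not printed. The list members ATF4, HSPA5 and HMOX1 were read in addition to this rule, after the results were seen. Marker lists were described by up to 4 members with the highest control level.

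The fits were tested on simulated data in which 100 genes were shifted by 1.5-fold and 100 by 2-fold. The other members of 1 gene list were shifted by a smaller amount. Noise was independent between genes and arrays, with 1 spread per gene taken from the real arrays of a table. Of the genes shifted by 1.5-fold, 97% were called in A549, 99% in THP-1 and 12% in J774. Of those shifted by 2-fold, 100% were called in A549, 100% in THP-1 and 81% in J774. Of all calls, those of the shifted list included, unchanged genes made up 7.69% in A549, 6.39% in THP-1 and 7% in J774. These rates hold for such noise only. Unequal spread of the human lines and the likeness of J774 arrays across the treatment were not simulated. Alternatives tried were an intensity trend with a robust prior, a new quantile normalization, median centring, no filter and a filter at the table's median, averaging a gene's probe sets, testing every probe set, and leaving out each array in turn. Others were the replicate number as a block, fitting a line's 4 arrays alone, other thresholds, and the other list tests.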

Results

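Gene expression was measured on 12 arrays, 2 for each of 6 groups, to compare cells exposed for 24 hours to 10 µg per mL of single-walled carbon nanotubes (SWCNT) with cells given water. The cells were A549 lung epithelial cells, PMA-differentiated THP-1 macrophages and J774 mouse macrophages. All changes below are SWCNT minus control on the log2 scale, with n = 2 arrays per group.

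Macrophage markers were high in the controls of both macrophage lines. In A549 controls the keratins KRT8, KRT7 and KRT18, structural proteins of epithelium, stood at mean log2 values of 13.38, 12.94 and 12.69. The epithelial list as a whole had a median of 7.90, at the 39.8 percentile of all genes in A549, no higher than its 7.99 in THP-1, at the 40.7 percentile. The macrophage list had a median of 7.25 in A549, at the 27.2 percentile. In THP-1 controls the macrophage list had a median of 12.2, at the 97.7 percentile, led by the signalling adaptor TYROBP at 13.85 and lysozyme (LYZ) at 13.80. In J774 controls it had a median of 11.6, at the 94.8 percentile of its own table, led by Fcer1g at 12.90 and Lyz2 at 12.56. The fibroblast list was high in J774 controls too, with a median of 9.81, at the 76.3 percentile. Its proteoglycan gene Dcn stood at 12.70, so the markers do not describe this line as macrophage alone. Levels were not compared between the human and mouse tables, which were normalized separately. Arrays of the same human group correlated across genes at r between 0.9963 and 0.9983, and no array duplicated another.

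The A549 comparison asks how lung epithelial cells responded to the nanotubes. The largest rise was in NIBAN1, a stress-inducible regulator of translation, which rose by 2.11 ± 0.07, or 4.32-fold (limma, Benjamini-Hochberg adjusted p = 9.37e-07). TRIB3 and DDIT3, a pseudokinase and a transcription factor of the integrated stress response, rose by 1.58 ± 0.09 and 1.26 ± 0.09. TXNIP, which binds thioredoxin and restrains glucose uptake, rose by 1.57 ± 0.09, and its arrestin relative ARRDC4 by 1.31 ± 0.08. CCL2, a chemokine that attracts monocytes, fell by 1.46 ± 0.10 on the log2 scale, or 2.74-fold in control over SWCNT (limma adjusted p = 5.56e-05).

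Among the other A549 genes with the largest rises were SMOC1, a secreted calcium-binding matrix protein, at 1.62 ± 0.11, and SPX, which encodes the peptide hormone spexin, at 1.61 ± 0.09. SLFN5 of the schlafen family rose by 1.51 ± 0.09, SNTB1, a syntrophin of the membrane skeleton, by 1.24 ± 0.09, and SMOX, which oxidises spermine, by 1.23 ± 0.10. The largest falls besides CCL2 were in GDA (guanine deaminase), at -1.39 ± 0.07, HMGCS1, a synthase of the mevalonate pathway, at -1.37 ± 0.12, and FGFBP1, a secreted carrier of fibroblast growth factors, at -1.35 ± 0.08. INSIG1, which holds SREBP proteins in the endoplasmic reticulum, changed by -1.34 ± 0.07. The secreted Wnt antagonist SFRP4 changed by -1.32 ± 0.13, APOH, a phospholipid-binding plasma protein, by -1.31 ± 0.12, and the matrix protease MMP7 by -1.29 ± 0.09. CLTRN, an amino acid transporter chaperone, changed by -1.26 ± 0.15, and CYP1B1, a monooxygenase induced through the aryl hydrocarbon receptor, by -1.22 ± 0.09. All 20 of these genes passed in each of the 16 refits tried.

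In all, 1579 of 15697 genes changed in A549 (limma adjusted p under 0.05), 703 higher and 876 lower. Of these, 118 were at least 1.5-fold higher and 183 at least 1.5-fold lower, while 22 and 17 reached 2-fold. The count was 685 without A549 control 2, 980 without A549 SWCNT 2, and 1046 and 1045 without THP-1 control 1 and 2, which share the estimate of spread. It was 662 when the 4 A549 arrays were fitted alone, against 742 for the 4 THP-1 arrays alone. Arrays of a group differed more in A549, with median SDs of 0.0644 in controls and 0.0761 under SWCNT. In THP-1 these SDs were 0.0425 and 0.0544. The shared fit gives both lines 1 spread per gene, so its counts do not show which line responded in more genes.

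**Figure D1:**
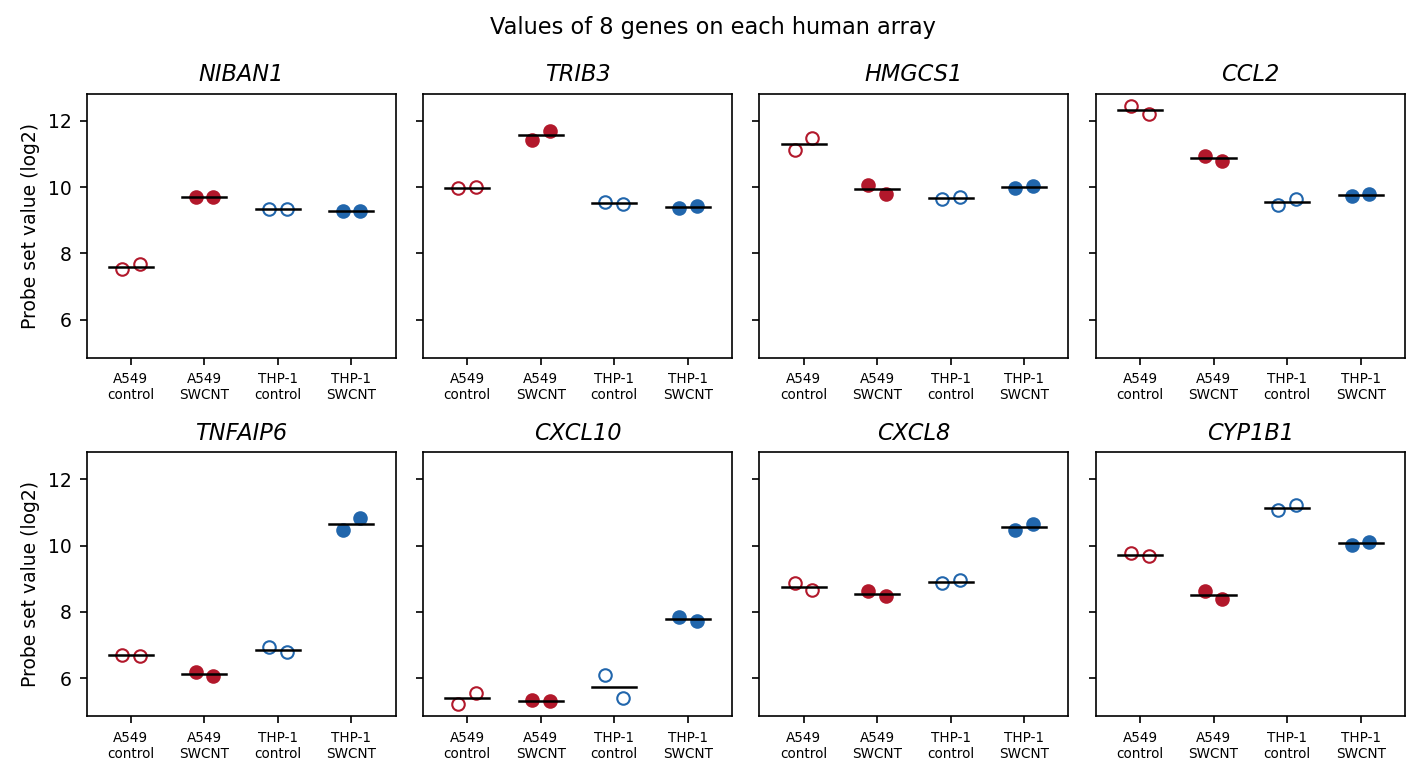
Probe set values (log2, vertical axis) of 8 genes on each human array, with A549 in red and THP-1 in blue, open circles for control arrays, filled circles for SWCNT arrays and bars for group means. NIBAN1 and TRIB3 rose in A549 by 2.11 and 1.58, TNFAIP6 rose in THP-1 by 3.80, and CYP1B1 changed by -1.22 in A549 and -1.07 in THP-1.

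Genes of the ATF4 and amino acid response, which act in amino acid supply and in restraining translation under stress, rose together in A549. Of 25 measured members 18 rose and 7 did not pass, and 20 rose when p was adjusted over the list alone. The median change was 0.62 (limma camera adjusted p = 5.67e-21, and adjusted p = 0.0384 with an estimated correlation). Besides TRIB3 and DDIT3, CHAC1, which degrades glutathione, rose by 1.16 ± 0.07 (limma adjusted p = 2.63e-05), and SESN2, a sensor of leucine and stress, by 1.12 ± 0.08. ATF4 itself measured 0.13 ± 0.12 (limma adjusted p = 0.597).

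Targets of p53 and DNA damage also rose in A549, with 5 of 22 members higher over all genes, 11 when adjusted over the list alone and a median of 0.24 (limma camera adjusted p = 0.00015; adjusted p = 0.0797 with an estimated correlation). The death receptor gene TNFRSF10B rose by 0.45 ± 0.07. Of 23 autophagy genes 8 rose over all genes and 8 adjusted over the list alone, with a median of 0.11 (limma camera adjusted p = 0.00234; adjusted p = 0.409 with an estimated correlation). They included the cargo receptors NBR1 and BNIP3L, at 0.89 ± 0.09 and 0.46 ± 0.08, and the ATG8-family gene GABARAPL1, at 0.44 ± 0.08. The autophagy call was lost without A549 SWCNT 1.

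Cell cycle genes fell together in A549. Of 30 measured members 25 fell and 5 did not pass, and 28 fell when adjusted over the list alone. The median change was -0.48 (limma camera adjusted p = 1.79e-21, and adjusted p = 0.0402 with an estimated correlation). CCNE2, a cyclin of the entry into S phase, fell by 0.85 ± 0.10 (limma adjusted p = 0.00082). The repressor E2F8 changed by -0.80 ± 0.08, the proliferation antigen MKI67 by -0.79 ± 0.11 and the replicative helicase subunit MCM4 by -0.64 ± 0.08.

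Genes of cholesterol biosynthesis fell in A549 as well. Of 19 measured members 11 fell over all genes and 12 adjusted over the list alone. The median was -0.36 (limma camera adjusted p = 1.4e-09, and adjusted p = 0.0384 with an estimated correlation). HMGCS1 and INSIG1 led this list, followed by the sterol carrier STARD4 at -0.81 ± 0.09 and ACAT2, which makes acetoacetyl-CoA, at -0.75 ± 0.08. Of 17 genes of fatty acid synthesis 6 fell over all genes and 7 adjusted over the list alone, with a median of -0.14 (limma camera adjusted p = 0.00234; adjusted p = 0.187 with an estimated correlation). The phosphatidate phosphatase LPIN1 changed by -0.65 ± 0.09, and the desaturases SCD and FADS2 by -0.41 ± 0.07 and -0.40 ± 0.07.

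Genes of the aryl hydrocarbon receptor and xenobiotic metabolism were lower in A549, 5 of 17 over all genes and 6 adjusted over the list alone, with a median of -0.10 (limma camera adjusted p = 0.0137; adjusted p = 0.187 with an estimated correlation). CYP1B1 and the receptor's feedback target TIPARP, at -0.99 ± 0.08, led them. Of 19 heat shock genes 5 fell over all genes, and adjusted over the list alone 6 fell and 1 rose, with a median of -0.08 (limma camera adjusted p = 0.0373; adjusted p = 0.574 with an estimated correlation). The chaperone HSPH1 fell by 0.44 ± 0.09 (limma adjusted p = 0.0124), a call lost without A549 control 2 or SWCNT 2. The calls of both lists were lost without A549 control 1 or SWCNT 1, and that of fatty acid synthesis without SWCNT 1. Of the 8 lists called in A549, 3 held with an estimated correlation, namely cell cycle, ATF4 and cholesterol biosynthesis, and 4 were called without A549 SWCNT 1.

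The THP-1 comparison asks the same of macrophage-like cells. TNFAIP6, a hyaluronan-binding protein induced by inflammatory cytokines, rose by 3.80 ± 0.12, or 13.9-fold (limma adjusted p = 2.17e-07), the largest rise in this line. The chemokines CXCL10, CCL4, CXCL8 and CCL20 rose by 2.06 ± 0.19, 1.83 ± 0.16, 1.66 ± 0.10 and 1.24 ± 0.10. SOD2, the mitochondrial superoxide dismutase, rose by 1.78 ± 0.08, and the NF-kB inhibitors TNFAIP3 and NFKBIA by 1.37 ± 0.07 and 1.23 ± 0.09. The costimulatory receptor TNFRSF9 rose by 1.62 ± 0.09 and EBI3, a cytokine subunit, by 1.41 ± 0.10.

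The largest fall in THP-1 was that of CYP1B1, at -1.07 ± 0.09 (limma adjusted p = 0.000303). Haptoglobin (HP) changed by -1.01 ± 0.12, the serpin SERPINB10 by -0.99 ± 0.13, the heparan sulfatase SULF2 by -0.96 ± 0.07 and MS4A3, a membrane protein of myeloid precursors, by -0.93 ± 0.12. The lysosomal fucosidase FUCA1 changed by -0.92 ± 0.07, and CCR2, the receptor for CCL2, by -0.82 ± 0.10. PHACTR3 and PPP1R27, regulators of protein phosphatase 1, changed by -0.87 ± 0.08 and -0.85 ± 0.08, and CMYA5 by -0.84 ± 0.09. All 20 named genes passed in each of the 16 refits tried.

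In all, 457 of 15697 genes changed in THP-1 (limma adjusted p under 0.05), 298 higher and 159 lower. Of these, 91 were at least 1.5-fold higher and 45 at least 1.5-fold lower, while 20 and 2 reached 2-fold. The count was 104 without THP-1 control 1, 121 without control 2, 157 without SWCNT 1 and 155 without SWCNT 2, and 742 when the 4 THP-1 arrays were fitted alone.

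Genes of NF-kB feedback and adhesion rose together in THP-1, with 13 of 17 members higher over all genes and 15 adjusted over the list alone. The median was 0.83 (limma camera adjusted p = 7.06e-29, and adjusted p = 0.0151 with an estimated correlation). Besides SOD2, TNFAIP3 and NFKBIA, the adhesion molecule ICAM1 rose by 1.01 ± 0.07 (limma adjusted p = 9.33e-05). Of 22 inflammatory cytokines and chemokines 8 rose over all genes and 11 adjusted over the list alone. Their median was 0.26 and their mean 0.59 (limma camera adjusted p = 1.45e-12, and adjusted p = 0.026 with an estimated correlation). NF-kB feedback and cytokines were the 2 lists of the 9 called in THP-1 that held with an estimated correlation. With that correlation 8 of the 35 lists had an unadjusted p under 0.05.

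Cell cycle genes rose in THP-1, with 12 of 30 members higher over all genes, 20 adjusted over the list alone and a median of 0.33 (limma camera adjusted p = 2.66e-18; adjusted p = 0.0556 with an estimated correlation). The mitotic checkpoint kinase BUB1 rose by 0.55 ± 0.07 (limma adjusted p = 0.00283), as did its relative BUB1B by 0.57 ± 0.08, whose call was lost without THP-1 control 2. Of 27 interferon-stimulated genes 3 rose over all genes and 13 adjusted over the list alone, with a median of 0.26 (limma camera adjusted p = 3.38e-08; adjusted p = 0.137 with an estimated correlation). The antiviral membrane protein IFITM1 rose by 0.76 ± 0.08. Of 15 antigen presentation genes 3 rose over all genes and 5 adjusted over the list alone, with a median of 0.12 (limma camera adjusted p = 0.0024; adjusted p = 0.137 with an estimated correlation), and this call was lost without THP-1 SWCNT 2. The costimulatory genes CD80 and CD40 rose by 1.07 ± 0.09 and 0.74 ± 0.09.

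Of 17 metallothionein and metal handling genes 5 rose and 1 fell over all genes in THP-1, 9 rose and 2 fell adjusted over the list alone, and the median was 0.41 (limma camera adjusted p = 1.46e-05; adjusted p = 0.14 with an estimated correlation). The metal-binding MT2A rose by 0.84 ± 0.10 and the zinc importer SLC39A8 by 0.83 ± 0.07. Of 19 cholesterol biosynthesis genes 1 rose over all genes, 6 rose and 1 fell adjusted over the list alone, and the median was 0.16 (limma camera adjusted p = 0.000694; adjusted p = 0.122 with an estimated correlation). The member that passed was lanosterol synthase (LSS), at 0.50 ± 0.10 (limma adjusted p = 0.0229), a call lost without any of the 4 THP-1 arrays.

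Of 19 genes of cholesterol efflux and lipid loading 1 rose and 1 fell in THP-1, over all genes and adjusted over the list alone, with a median of -0.17 (limma camera adjusted p = 0.00872; adjusted p = 0.14 with an estimated correlation). The sterol receptor gene NR1H3 rose by 0.66 ± 0.08, and PDK4, a kinase that restrains glucose oxidation, changed by -0.64 ± 0.09, a call lost without THP-1 control 2 or SWCNT 1. The lysosome list had a median of -0.09 (limma camera adjusted p = 0.0109; adjusted p = 0.255 with an estimated correlation), with 0 of 26 members past the limma test and 3 lower at an unadjusted p under 0.05. Its call was lost without THP-1 SWCNT 1 and after a new quantile normalization.

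**Figure D2:**
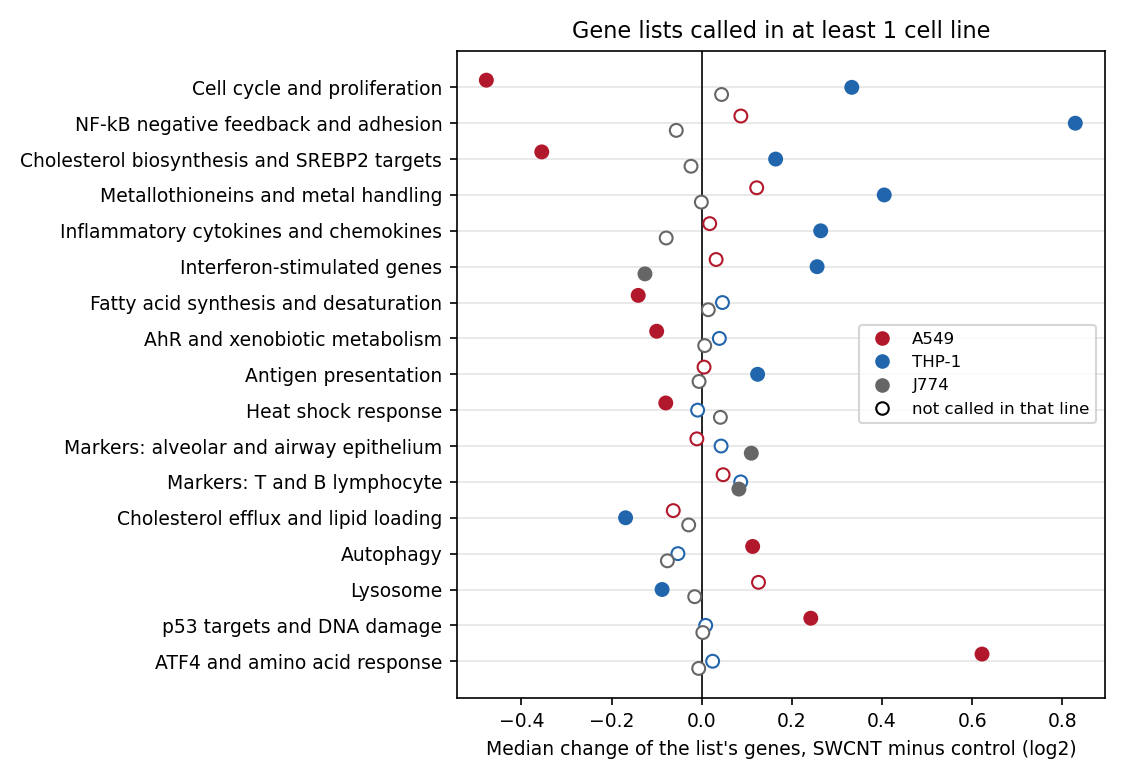
Median log2 change (horizontal axis, SWCNT minus control) of the 17 gene lists called in at least 1 line, with A549 in red, THP-1 in blue and J774 in grey, filled where limma camera called the list in that line and open where it did not. The cell cycle medians were -0.48 in A549 and 0.33 in THP-1, the ATF4 median was 0.62 in A549, and the NF-kB median was 0.83 in THP-1.

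Whether the human lines responded differently was tested as an interaction. The THP-1 change of TNFAIP6 lay 4.35 ± 0.16 above its A549 change (limma adjusted p = 1.76e-06), which was a fall of 0.55 (limma adjusted p = 0.0149). For CXCL10 and CXCL8 the THP-1 change lay above the A549 change by 2.12 ± 0.27 and 1.88 ± 0.14. FAM111B, a protease, differed by 1.94 ± 0.11 and SOD2 by 1.82 ± 0.12. In the other direction NIBAN1 differed by -2.17 ± 0.10, TRIB3 by -1.70 ± 0.13, TXNIP by -1.66 ± 0.13, NUPR1, a stress-induced chromatin protein, by -1.61 ± 0.17 and SMOC1 by -1.59 ± 0.16. All 10 passed in each of the 15 refits tried.

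The response differed between the lines in 1139 of 15697 genes (limma adjusted p under 0.05), with the THP-1 change above the A549 change in 654 and below it in 485. Of the 1139, 684 were called in A549 alone, 199 in THP-1 alone, 99 in both and 157 in neither, and 97 of the 99 had opposite signs. That share follows largely from the selection, because the interaction test favours genes that moved in opposite directions. The count was 756 without A549 control 2, 527 and 510 without THP-1 control 1 and 2, and 603 and 661 without THP-1 SWCNT 1 and 2.

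Of the 35 lists 13 differed between the lines with camera and 5 of these also with an estimated correlation. Cell cycle genes differed by a median of 0.79 (limma camera adjusted p = 2.81e-29, and adjusted p = 0.0225 with an estimated correlation). Of these genes 27 of 30 were past the limma test and 30 adjusted over the list alone. MKI67, KIF11, a mitotic motor, and E2F8 differed by 1.19 ± 0.16, 1.14 ± 0.13 and 1.12 ± 0.11. NF-kB feedback genes differed by a median of 0.79, with 12 of 17 members past the test and 13 adjusted over the list alone, and cytokines by 0.23, with 7 of 22 and 9. Cholesterol biosynthesis genes differed by a median of 0.56, with 10 of 19 members higher, and adjusted over the list alone 14 higher and 1 lower. HMGCS1 differed by 1.72 ± 0.17 and INSIG1 by 1.43 ± 0.10. The ATF4 list differed by a median of -0.57, with 14 of 25 members past the test and 21 adjusted over the list alone, among them DDIT3 at -1.42 ± 0.13 and the lipoprotein receptor VLDLR at -1.28 ± 0.13.

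**Figure D3:**
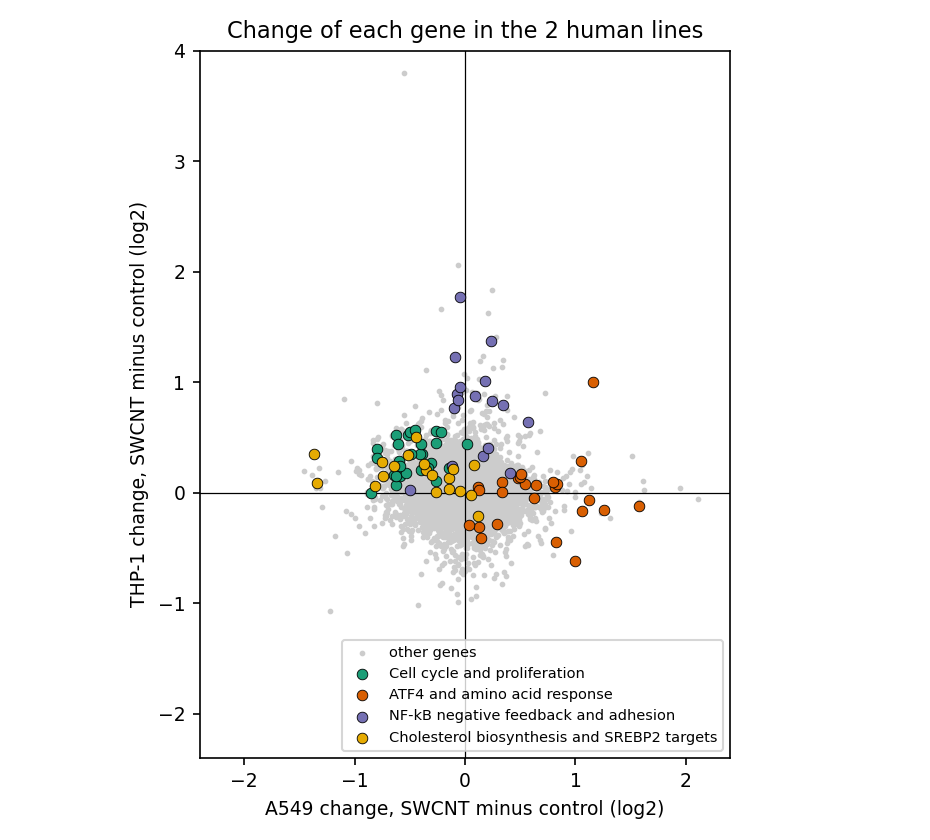
Change of each gene in A549 (horizontal axis, log2) against its change in THP-1 (vertical axis, log2), with members of 4 gene lists coloured and other genes in grey. Across the 15697 genes r was -0.05, while cell cycle genes lay at a median of -0.48 in A549 and 0.33 in THP-1.

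Across genes the changes in A549 and THP-1 were nearly unrelated, with Pearson r of -0.0539 and Spearman rho of -0.0255 over 15697 genes, which are not independent replicates. Pearson r was -0.0287 without A549 control 1, -0.0179 without A549 SWCNT 1 and -0.0868 without A549 SWCNT 2. Genes that fell in A549 and rose in THP-1 numbered 81 against 16.6 for independent lists (Fisher's exact test, adjusted p = 1.14e-33 over 4 tests), and genes that rose in A549 and fell in THP-1 numbered 16 against 7.12 (adjusted p = 0.00548). They included FAM111B, at -1.09 in A549 and 0.85 in THP-1, EMP2, a tetraspan membrane protein, at -0.80 and 0.81, and the midbody gene CEP55, at -0.55 and 0.70. Genes higher in both lines numbered 20 against 13.3 (adjusted p = 0.0872) and genes lower in both 9 against 8.87 (adjusted p = 0.863). The expected numbers and p-values are approximate, because both sets of calls come from 1 fit with shared gene-wise variances and Fisher's exact test takes co-regulated genes as independent. CHAC1 rose in both, by 1.16 in A549 and 1.01 in THP-1, and CYP1B1 changed by -1.22 and -1.07.

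The J774 comparison asks how mouse macrophages responded. Macrophage genes differed more within a treatment than between treatments: the median of the macrophage list, relative to its mean over the 4 arrays, was -0.24 in control 1, 0.32 in control 2, 0.35 in SWCNT 1 and -0.49 in SWCNT 2. Scavenger receptors followed the same order, at -0.17, 0.24, 0.25 and -0.32. Across genes control 1 correlated with SWCNT 2 at r = 0.9978 and control 2 with SWCNT 1 at r = 0.9974, while the controls correlated with each other at 0.9943 and the SWCNT arrays at 0.9941. Against this spread 0 of 15044 genes passed limma's test, and 295 had an unadjusted p under 0.05, or 1.96% of those tested.

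The largest J774 changes did not pass in the fit without a block. Scarna13, a small Cajal body RNA, measured 1.90 ± 0.16 (limma adjusted p = 1, unadjusted p = 0.000216), and the nuclear noncoding RNA Malat1 measured 0.79 ± 0.12. Ubl5, a ubiquitin-like splicing protein, measured -0.81 ± 0.21, Tbc1d7, a subunit of the TSC complex, -0.79 ± 0.25, and the small heat shock protein Hspb1 -0.51 ± 0.15. Fam98b measured 0.67 ± 0.25, Wfdc13 -0.73 ± 0.13 and Lgals9, a galectin, -0.53 ± 0.19.

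Camera called 3 lists in J774. The interferon-stimulated list had a median of -0.13 over 23 members (limma camera adjusted p = 0.00109; adjusted p = 0.915 with an estimated correlation), with Isg20, an exonuclease, at -0.37 ± 0.12. The epithelial markers had a median of 0.11 over 16 members and the lymphocyte markers 0.08 over 8 (limma camera adjusted p = 0.024 and 0.0341; adjusted p = 0.915 for both with an estimated correlation). These are markers of other cell types, with control medians of 6.80 and 6.51, at the 33.7 and 27.4 percentiles of J774 genes, and fibroblast markers measured 0.13 (limma camera adjusted p = 0.238). The macrophage markers, the line's own, were not called, with a median of -0.14 over 20 members, about that of the interferon list (limma camera adjusted p = 0.255; adjusted p = 0.915 with an estimated correlation). With an estimated correlation 0 of the 35 lists passed, and with fry 0 passed, while 1 list in each had an unadjusted p under 0.05. Camera with an estimated correlation has 2 residual degrees of freedom here, so it cannot tell whether the calls rest on correlated genes. For the interferon list the estimated correlation was -0.0262, below the preset one. Its unadjusted camera p still rose from 3.1e-05 to 0.0441. All 3 calls were lost without control 1 or without SWCNT 1, where 1 and 2 other lists were called. Without SWCNT 2 the interferon call alone was kept among 5 lists, and without control 2 all 3 were kept among 8. The interferon list was the 1 list called after a new quantile normalization. It was also the 1 list called with a filter at the table's median, where the epithelial and lymphocyte lists kept too few members to be tested.

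**Figure D4:**
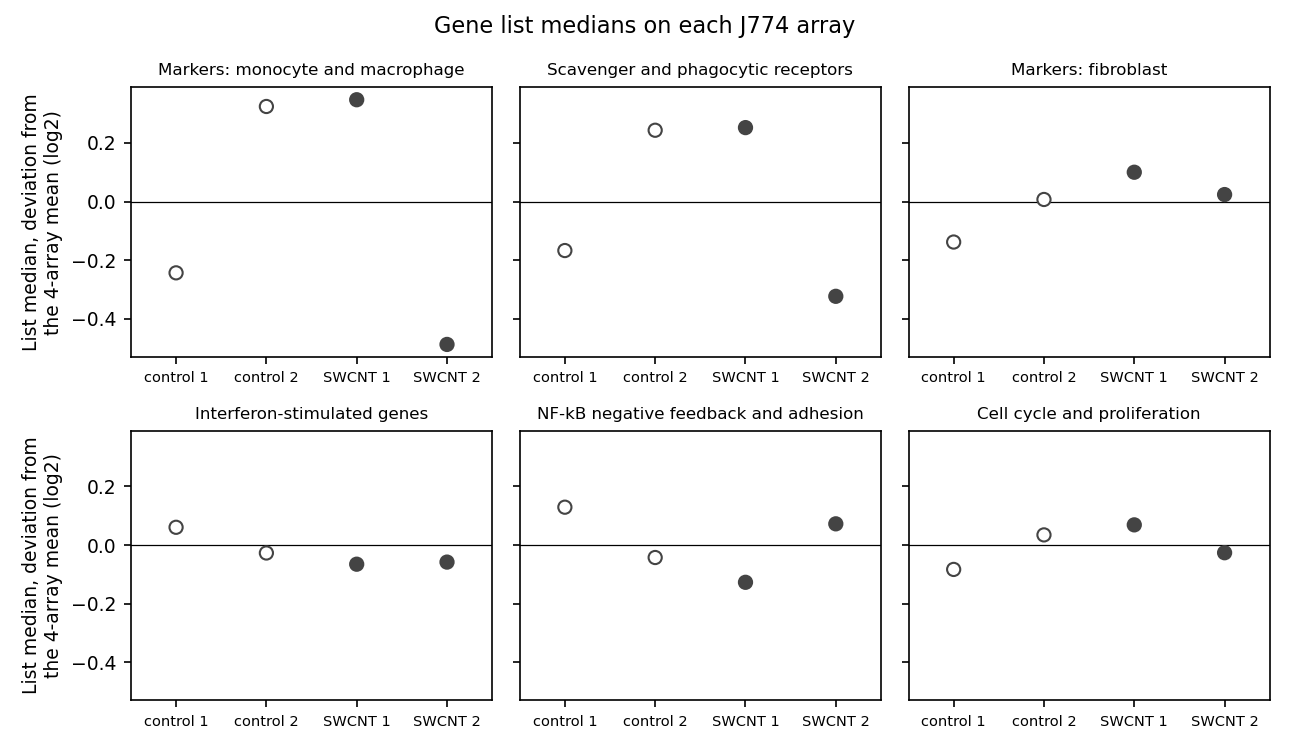
Median of 6 gene lists on each J774 array, as the deviation from the mean of the 4 arrays (log2, vertical axis), with open circles for control arrays and filled circles for SWCNT arrays. The macrophage list stood at -0.24 and 0.32 in the controls and at 0.35 and -0.49 in the SWCNT arrays.

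Changes in J774 had Pearson r of -0.00103 with those of THP-1 and -0.0667 with those of A549 across 11771 genes matched by symbol, which are not independent replicates; the latter was 0.0441 without J774 control 2 and 0.0487 without SWCNT 2. The former was -0.027 without THP-1 SWCNT 1 and 0.0227 without THP-1 SWCNT 2. With 0 genes called in J774 by limma, no overlap of calls could be formed with either human line. Whether the J774 response differed from a human one was not tested.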

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

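All tests of explanations below were chosen only after the results they bear on had been seen; the interaction test between the human lines was chosen earlier, and its application to gene lists later. Results singled out by it were those in which THP-1 and A549 responded differently to the same exposure.

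The response differed in 1139 genes. The THP-1 change exceeded the A549 change by 4.35 for TNFAIP6, 2.12 for CXCL10, 1.94 for FAM111B, 1.88 for CXCL8 and 1.82 for SOD2, and lay below it for NIBAN1 (-2.17), TRIB3 (-1.70), TXNIP (-1.66), NUPR1 (-1.61) and SMOC1 (-1.59). Median differences were 0.79 for the cell cycle list, 0.79 for NF-kB feedback, 0.56 for cholesterol biosynthesis, 0.23 for cytokines and -0.57 for the ATF4 list, all of which held with an estimated correlation. They were 0.35 for metallothioneins, 0.23 for interferon-stimulated genes, 0.25 for fatty acid synthesis, 0.24 for aryl hydrocarbon receptor genes, 0.15 for antigen presentation, -0.21 for p53 targets, -0.19 for lysosome and -0.0349 for autophagy. These calls were lost with an estimated correlation, with adjusted p = 0.34 for metallothioneins, interferon-stimulated genes and autophagy, 0.112 for fatty acid synthesis and p53 targets, 0.159 for aryl hydrocarbon receptor genes and lysosome, and 0.166 for antigen presentation (limma camera). The version with an estimated correlation has fewer degrees of freedom, so its loss of these calls need not reflect correlated genes. The autophagy list's mean difference was -0.18.

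Cell cycle genes fell in A549 and rose in THP-1 (limma camera, adjusted p = 0.0402 and adjusted p = 0.0556 with an estimated correlation, so that the THP-1 call was lost). The tables argue against an intensity-dependent shift left by the normalization: among 10000 random lists matched on mean log2 value the lowest median in A549 was -0.194, against -0.478 observed, and the highest in THP-1 was 0.0908, against 0.333. More undifferentiated THP-1 cells in the SWCNT flasks would be predicted to raise early myeloid genes. A list of 18 such genes instead had a median change of -0.371, with 8 lower and 0 higher (limma camera p = 1.58e-14, and p = 0.0048 with an estimated correlation). The list was chosen after its members MS4A3 and SERPINB10 had been seen to fall. A response of its members to SWCNT could also hide a changed share of cells, so the list cannot settle this explanation. Opposite proliferative responses of the lines remain a candidate explanation that was not tested apart from these genes, and a difference in density or culture between flasks stays open.

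ATF4 target genes rose in A549. An intensity-dependent shift is argued against, since the highest median among 10000 matched random lists was 0.147, against 0.622 observed. An unfolded protein response of the endoplasmic reticulum stays open: the list of its chaperones had a median of 0.0629 with members on both sides of 0. Over all genes 5 of its 21 members were higher and 1 was lower. XBP1, SEL1L and HERPUD1 rose by 0.71 ± 0.11, 0.57 ± 0.09 and 0.44 ± 0.08. The chaperone HYOU1 rose by 0.39 ± 0.07, while the chaperone HSPA5 measured 0.15 ± 0.07. Nutrient stress may give the same pattern, and no biological explanation other than the unfolded protein response was tested.

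The J774 arrays were alike across the treatment rather than within it. The real split called 0 genes, and exchanging the labels of SWCNT 2 and control 2 called 2443, which points to a structure of the samples but restates the likeness of the arrays rather than testing it. The 3 splits of 4 arrays are too few to judge chance. Exchanged labels stay open as a candidate explanation: the exchanged split had r = -0.0039 with the THP-1 change and 0.116 with the A549 change, against -0.00103 and -0.0667 as labelled, and mouse cells need not respond as human ones did. A varying share of fibroblast-like cells stays open too: in the array with the lower macrophage list the fibroblast markers had median differences of -0.133 (SD 0.343, n = 13 genes) among the SWCNT arrays and -0.144 among the controls, where a larger share would raise them, yet only 8 and 9 of the 13 were lower; S100a4 and Dcn stood at 12.71 and 12.70 in controls. Shared handling that crossed the treatment cannot be told apart from these, as deviations of same-numbered arrays correlated at -0.818 and the labels give no batch.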

How the results depend on the processing

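The crossed pairing and all alternatives for list counts of the difference were chosen after seeing the data. All 20 named genes of each human line and all 10 of the difference kept their calls in every refit. Over all named genes, lists and list members with a call, no call changed direction; 244 of 2127 gene refits in A549, 196 of 1373 in THP-1 and 138 of 1196 for the difference lost the call. Refits without an array assume that the lone array varies like the other groups.

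The A549 count of 1579 was 662 with its 4 arrays alone, 301 with a 1.5-fold minimum, 308 with that minimum and unadjusted p, 2491 at an adjusted p under 0.1, and 685 (without control 2) to 2118 (without SWCNT 1) with an array left out. In THP-1 457 became 742, 136, 145 and 726, and 104 to 586. For the difference 1139 became 656 with the minimum, 7.4e2 with unadjusted p (462 higher and 282 lower), 1790 at 0.1, and 510 to 1570. The J774 count stayed 0 with every array left out and was 11 at an unadjusted p with the minimum. Higher genes were 44.5% of A549 calls and 52.2% without SWCNT 2. The causes were not tested, except that looser or stricter thresholds change counts by construction.

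Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.116 in A549, 0.0282 in THP-1 and -0.818 in J774. With the replicate block 1046 genes were called in A549, 247 in THP-1, 773 for the difference and 0 in J774 (295 at an unadjusted p under 0.05 without the block), and list counts did not change. With crossed numbers limma called 2165 genes in A549 and 5 in J774, where it called 0.

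With an estimated correlation the lists called numbered 3 in A549, 2 in THP-1 and 5 for the difference. In J774, where that version has 2 residual degrees of freedom, they numbered 0 (1 at an unadjusted p). Fry called 0 in J774 (1 unadjusted). The J774 count of 3 was 1 after quantile normalization and 1 with the median filter, which left the epithelial and lymphocyte markers untested. Leaving out an array gave 4 to 9 lists in A549, 8 to 10 in THP-1, 1 to 8 in J774 and 10 to 14 for the difference.

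The correlation of A549 with THP-1 ranged from -0.0868 to -0.0179 and of A549 with J774 from -0.121 to 0.0487 over left-out arrays. That of THP-1 with J774, -0.00103, ranged from -0.027 to 0.0227, and was -0.0229 after quantile normalization, -0.0219 with the median filter and -0.0383 over genes at an unadjusted p under 0.05. Rescaling moved the median change of all genes to at most 0.00504 and at least -0.0171. Dim genes near the floor limit small folds.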

Other observations

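The level comparisons below were fixed with the gene lists; which of their members to describe was decided after the values were seen.

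In A549 several lists had members on both sides without a call by limma camera. The ER chaperone list had 5 higher and 1 lower of 21 members (7 and 2 adjusted over the list alone), with XBP1, a transcription factor of secretory cells, at 0.71 ± 0.11, SEL1L, of endoplasmic reticulum degradation, at 0.57 ± 0.09 and HERPUD1 at 0.44 ± 0.08. The prostaglandin and leukotriene list, which limma's fry called (adjusted p = 0.0347), had 2 higher and 4 lower of 16 (2 and 5 adjusted over the list alone). Its largest change was a rise of ALOX5AP, by 0.69 ± 0.16. HPGD, which inactivates prostaglandins, thromboxane synthase TBXAS1 and the cyclooxygenase PTGS2 changed by -0.66 ± 0.10, -0.55 ± 0.07 and -0.49 ± 0.08. The lysosome list had 7 higher and 2 lower of 26 (the same adjusted over the list alone), with the peptidase TPP1 at 0.57 ± 0.09 and cathepsin S (CTSS) at -0.66 ± 0.09.

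Targets of NRF2, the regulator of the oxidative stress response, had a median of 1.21e-05 in A549 and 0.05 in THP-1, with 2 higher and 1 lower of 24 in A549 (3 and 2 adjusted over the list alone) and 0 of 24 past the limma test in THP-1. The haem oxygenase HMOX1 measured 0.27 ± 0.09 in A549 (limma adjusted p = 0.0755). In the inflammasome list IL1B and the ATP receptor P2RX7 rose by 0.92 ± 0.07 and 0.92 ± 0.11 in THP-1, while TXNIP rose by 1.57 ± 0.09 in A549, and the list medians were -0.08 and -0.06.

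The 18 lists that limma camera called in no line had medians from -0.11 to 0.12 in A549, -0.10 to 0.11 in THP-1 and -0.14 to 0.13 in J774. They were actin cytoskeleton, antioxidant enzymes, apoptosis, ribosomal proteins, ER chaperones, extracellular matrix, glycolysis, immediate early genes, inflammasome, metalloproteinases, NRF2, oxidative phosphorylation, prostaglandins, scavenger receptors, and markers of endothelium, fibroblasts, macrophages and neutrophils. Among these, limma's fry called antioxidant enzymes in A549 and THP-1 (adjusted p = 0.0419 and 0.0411), prostaglandins in A549 and fibroblast markers in THP-1 (adjusted p = 0.0324). Of 18 antioxidant genes 2 passed the limma test in A549, with a list median of 0.03. In THP-1 1 passed, with a list median of -0.007, namely SOD2, which is also in the NF-kB list.

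In J774 controls the fibroblast list had a median of 9.81, at the 76.3 percentile, with S100a4 at 12.71 ± 0.24, Dcn, a collagen-binding proteoglycan, at 12.70 ± 0.57, Pdgfra at 10.92 ± 0.32 and Col1a2 at 10.60 ± 0.10 (SD, n = 2). S100a4 is also expressed by macrophages. In THP-1 controls the neutrophil list had a median of 9.72, at the 72.0 percentile. It was led by S100A8 at 12.83, S100A9 at 11.88, ELANE at 11.74 and PRTN3 at 11.26. ELANE and PRTN3 are also in the early myeloid list, so these levels do not mark neutrophils alone.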
